A study of Strongylocentrotus purpuratus with 3 samples.

How the data were processed

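Embryos of the purple sea urchin were dissociated into single cells and 3 droplet libraries were made with the 10x Genomics Chromium 3′ v2 chemistry, 1 from embryos given DMSO, 1 from embryos given 8 µM DAPT from fertilization on and 1 labelled as having no treatment; about 5000 cells were targeted for each, per the labels. The deposited tables hold whole-number counts of unique molecular identifiers (UMIs) for 32262 gene names by cell barcode, 1 table per library, with no normalization by the authors in the values. The submitters' processing notes name Cell Ranger, with no version, and Seurat 2.3.0; the aligner settings, the genome build and the annotation were not given in the sources used here. Which barcodes the authors kept was not stated; in the tables the lowest number per barcode was 420 for UMIs and 219 for detected genes. Of the gene names, 278 are symbols and 30897 are numbered LOC identifiers, and 3 of the latter have a symbol in the reference gene table. Gene positions are not printed because the build is not known.

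All 3348 DMSO, 2686 DAPT and 2228 untreated barcodes had at least 200 detected genes and were kept. For clustering, the counts of each cell were scaled to 10000 and log-transformed with 1 added, and 2000 variable genes were ranked by library with scanpy 1.11.5. The values were standardised, reduced to 30 principal components, joined to 15 nearest neighbours, and partitioned with leidenalg 0.10.2 at resolution 1.0, with no batch integration. Scrublet scores called 20 of 8262 barcodes as doublets (12 in DMSO, 6 in DAPT and 2 in untreated), too few for the caller to be taken as having worked, so called barcodes were kept. Barcodes of very high UMI count remain in the data (up to 33694 UMIs in DAPT), and removing the 5% of barcodes with the most UMIs in each library (415 barcodes) was added as an alternative after the data were seen.

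Cell classes were named from marker lists fixed before the data were examined: 119 markers in 9 lists, of which 49 matched a gene name, 4 of them by a spelling or identifier added after the names were seen. A marker counted as raised in a cluster at 2-fold or more over all other cells, with 10 CPM (counts scaled to a total of 1000000) added to both, and at least 5 UMIs. A cluster took the name of the list with the most raised markers if it had at least 3 and more than any other list. These thresholds were set after the data were seen. The minimum of 5 UMIs took the name aboral-ectoderm-like from cluster 19, which held 0.657% of DMSO, 0.484% of DAPT and 0.314% of untreated cells. Clusters that this rule left unnamed were called the gcm cluster or the delta cluster when that gene was at least 5-fold higher with at least 20 UMIs; the genes, the thresholds and the use of gcm alone for its cluster were also decided after the data and results were seen. Pigment cells could not be named, since fewer than 3 of 11 pigment markers matched, and neither could muscle cells, since none of 10 did. No marker of the blastocoelar-like cluster was among its 10 most raised genes. Since the genes that define clusters differ between libraries, class shares are printed also from a clustering that left out the 12107 genes at least 2-fold apart between any pair of libraries. Its clusters were still named with all genes.

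Each group has 1 library, so no test was made and no paired analysis was possible; cells were not treated as replicates. Raw counts were summed over all cells of a library or class and expressed as CPM. Sums have exact Poisson 95% intervals, ratios exact conditional binomial intervals and shares of cells Clopper-Pearson intervals (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). A count of 0 was set to 3 counts for a ratio, which then is a bound. For DAPT over DMSO, the rule for named genes took the 10 largest ratios each way among genes with a symbol, at least 50 UMIs over the 3 libraries, at least 2-fold from DMSO with an interval excluding 1, and at least 1.5-fold the same way from untreated; 4 genes that were higher and 3 that were lower are reported. For DMSO over untreated it took the 5 largest ratios each way at 2-fold or more. Some genes that these rules picked are not reported here. Within a named class of at least 50 cells per library the rule took the 3 largest each way. These needed at least 30 UMIs over DAPT and DMSO, 2-fold from DMSO and 1.5-fold the same way from untreated. Classes of at least 30 cells were added after the data were seen, together with the delta cluster. In each list the rule took up to 4 members with at least 30 UMIs over the pair, those farthest from 0. The gene delta and the gcm gene were always given, and so would notch, suh, hesc and pks1 have been, but no gene name matched them. For each list of at least 3 measured members, the median log2 ratio was set against 10000 random lists of equal size drawn from 20 bins of mean expression, as a description of these libraries.

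To compare shares of cells with a UMI, each cell was thinned at random to 514 UMIs, the 10th percentile of the DAPT library, and 266 DAPT cells with fewer were left out. The intervals were tested on counts drawn from a Poisson distribution at the depths of these libraries, with 200 genes set apart. They held the true ratio for 95.9% of 7850 genes for DAPT over DMSO and for 95.9% of 8903 genes for DMSO over untreated. Exact intervals hold the true ratio of Poisson counts by construction, and such draws leave out differences between cells and between cultures. The simulation therefore checks the calculation and not the spread of these data. For DAPT over DMSO, a true log2 ratio of -1 gave an interval on the right side of 1 for 72% of 50 genes, and a true ratio of 1 for 90%. For DMSO over untreated these were 76% and 96%, so that lower genes were seen less often than higher genes in both comparisons.

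The alternatives were a minimum of 500 detected genes, removal of Scrublet calls, resolutions of 0.5 and 2.0, each library clustered on its own, clustering without the genes 2-fold apart, median-of-ratios scaling, CPM without the 50 most abundant genes, the mean over cells of each cell's CPM, minimums of 10 or no UMIs for named genes and of 10 for list members, 2-fold in place of 1.5-fold, untreated in place of DMSO for the lists and within classes, at least 2 UMIs in place of 1, and thinning. The choice of which results answer a comparison, for the account of these alternatives, was made after the data were seen. Figures were drawn with matplotlib 3.10.9.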

Results

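Single-cell RNA-seq profiles were collected from dissociated embryos of the purple sea urchin with a droplet-based 3′ assay that counts unique molecular identifiers (UMIs), so that each count stands for 1 captured transcript. There were 3 libraries, 1 per group: embryos given DAPT, embryos given DMSO, and embryos labelled as having no treatment, called untreated here. DAPT is a gamma-secretase inhibitor that blocks the cleavage of the Notch receptor, and it was added at fertilization to 8 µM; DMSO is its solvent. The libraries held 3348 (DMSO), 2686 (DAPT) and 2228 (untreated) cell barcodes, with 4560733, 2618815 and 4798419 UMIs in all. The median barcode had 1224 UMIs and 571 detected genes in DMSO, 808 and 454 in DAPT, and 1529 and 680.5 in untreated. The embryonic stage was not given in the sources used here: the stage label reads adult, whereas the protocol describes embryos. That protocol also describes C59, an inhibitor of Wnt secretion, which no treatment label of these 3 libraries names. The title of the library labelled as having no treatment begins with W, which the sources used here do not explain. Each value over untreated rests on that label. With 1 library per group there were no replicates, so no test was made, and each 95% interval below covers counting error only.

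The clustering of all 8262 barcodes gave 21 clusters, and markers fixed beforehand named 5 of them. The oral-ectoderm-like cluster expressed Chordin (CHRD) and Not, the apical-neurogenic-like cluster foxq2 and AnkAT-1, the endoderm-like cluster Endo16, blimp1/krox and GATAe, the skeletogenic-like cluster the spicule matrix genes SM30A, SM50 and SM37, and the blastocoelar-like cluster GATAc and erg. The blastocoelar markers were not particular to the latter: GATAc, erg, c3 and SRC8 were raised in the skeletogenic-like cluster too, with erg at 429 CPM (counts scaled to a total of 1000000) there in DMSO against 121 in the blastocoelar-like cells. Cluster 8 was singled out by gcm and cluster 10 by delta. These are called the gcm cluster and the delta cluster, since no list of fixed markers met the naming rule in either. Of the pigment markers, only 2 of 11 matched a gene name. The remaining 14 clusters stayed unnamed. They held most cells of each library: 2349 of 3348 in DMSO, 1689 of 2686 in DAPT and 1455 of 2228 in untreated. The classes named above thus cover the smaller part of the cells. Among the unnamed clusters was cluster 17, with 45 untreated, 21 DMSO and no DAPT cells. In it gcm was raised with too few UMIs for the name. Cluster 3 held 21.9% of untreated cells against 3.08% of DMSO cells and 1.45% of DAPT cells. Cluster 1 went the other way, with 3.19% of untreated cells against 21.0% of DMSO cells and 18.1% of DAPT cells. With 1 library per group such a difference cannot be told from a property of a library.

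The comparison of DAPT with DMSO asks which embryonic cells and genes depend on Delta/Notch signalling, the subject given in the title of the study. Cells of the gcm cluster were nearly missing from the DAPT library (gcm encodes a transcription factor of the pigment cell lineage). They made up 0.596% of DAPT cells (16 of 2686, 0.341% to 0.966%), 6.66% of DMSO cells (5.84% to 7.56%) and 3.01% of untreated cells (2.34% to 3.80%), a share 11.2-fold lower in DAPT than in DMSO (log2 ratio -3.48, -4.31 to -2.75). Cells of the delta cluster were 3.81-fold more frequent in DAPT than in DMSO (2.76 to 5.34), at 5.81% (4.95% to 6.76%) against 1.52% (1.14% to 2.00%), with 1.93% in untreated (1.40% to 2.59%). Endoderm-like cells made up 10.5% of DAPT cells (9.36% to 11.7%) and 6.12% of DMSO cells (5.33% to 6.99%), a ratio of 1.71 (1.43 to 2.06). Oral-ectoderm-like cells were 1.61-fold more frequent in DAPT (1.36 to 1.89), at 12.8% against 7.97%.

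For 3 classes the ratio of DAPT to DMSO had an interval that included 1 in the joint clustering at resolution 1.0. Skeletogenic-like cells made up 3.31% of DAPT and 2.84% of DMSO cells (ratio 1.17, 0.865 to 1.58), and apical-neurogenic-like cells 2.42% and 2.45% (ratio 0.988, 0.702 to 1.39). With each library clustered on its own the latter ratio was 0.582 (0.445 to 0.757). Blastocoelar-like cells made up 1.68% of DAPT and 2.27% of DMSO cells (ratio 0.738, 0.499 to 1.08). That ratio was 0.539 (0.313 to 0.889) among cells with at least 500 genes and 0.113 (0.00263 to 0.780) at resolution 2.0, where the class held 1 DAPT and 11 DMSO cells. The class was not resolved when the clustering left out the genes that differed at least 2-fold between any libraries. The grouping of cells did not use the differing genes there, but the naming of clusters did, by gcm and delta among others. This clustering gave 0.596%, 6.90% and 4.85% for the gcm cluster in DAPT, DMSO and untreated. For the delta cluster it gave 3.28%, 1.14% and 1.62%. Endoderm-like cells then made up 10.3%, 5.85% and 1.93%, oral-ectoderm-like cells 14.1%, 9.32% and 9.16%, skeletogenic-like cells 3.24%, 2.75% and 1.71%, and apical-neurogenic-like cells 1.64%, 1.79% and 11.4% in the same order.

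**Figure D1:**
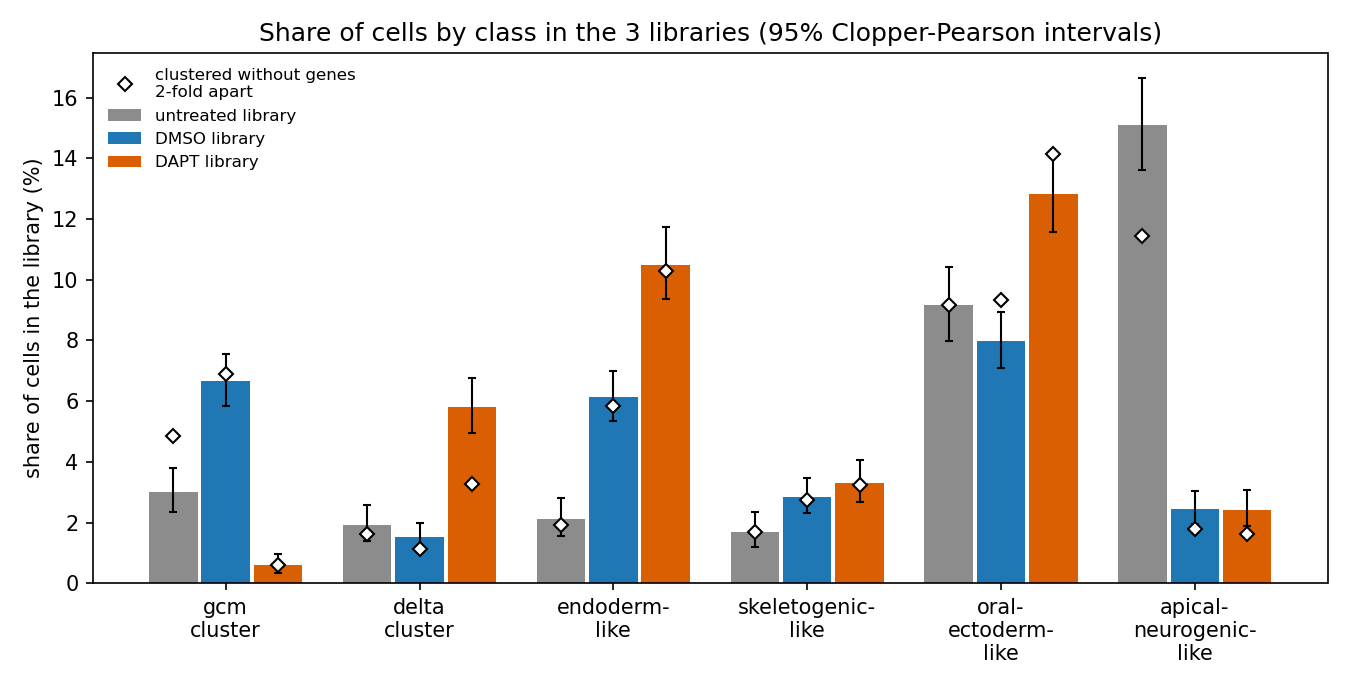
Share of cells (%) in 6 classes for the untreated (grey), DMSO (blue) and DAPT (orange) libraries; bars give the share, error bars the 95% Clopper-Pearson interval, and diamonds the share when the clustering left out the genes at least 2-fold apart between libraries. The gcm cluster held 0.596% of DAPT cells against 6.66% of DMSO cells, and the apical-neurogenic-like class held 15.1% of untreated cells against 2.45% of DMSO cells.

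Over whole libraries, gcm was 8.20-fold lower in DAPT than in DMSO (2.67 against 21.9 CPM, log2 -3.04, -4.39 to -1.94). All 7 gcm UMIs of the DAPT library lay in the 16 cells of the gcm cluster, where gcm stood at 393 CPM (158 to 810) against 199 in DMSO (157 to 248). This cluster held 78.0% of the gcm UMIs of DMSO but 40.3% of those of untreated, where 44.2% lay in unnamed clusters, so its share ratios over untreated leave out part of the cells with gcm. Other genes that the rule for naming picked as lower had few UMIs: tmem16, of the anoctamin family of channels and scramblases (8 in DAPT and 49 in DMSO, log2 -1.81, -3.10 to -0.72) and the signalling ligand Wnt8 (5 and 29, log2 -1.74, -3.46 to -0.35). Of the unnamed loci, chosen after their values were seen, LOC577816 (log2 -5.29, -10.61 to -2.76) and LOC590330 (log2 -4.93, -7.99 to -3.04) were the lowest, and 59.5% and 59.4% of their UMIs over the 3 libraries lay in the gcm cluster.

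The genes that the rule picked as higher in DAPT were Endo16, which encodes a surface protein of the gut (2.92-fold, log2 1.55, 1.36 to 1.74), the ETS factor erg (2.17-fold, log2 1.12, 0.76 to 1.48), and the endoderm regulators blimp1/krox (2.08-fold, log2 1.05, 0.91 to 1.20) and GATAe (2.06-fold, log2 1.04, 0.68 to 1.40). AnkAT-1 (log2 1.31) and delta (1.25) passed the conditions over DMSO but not the one over untreated (-2.70 and 0.42). For blimp1/krox and GATAe untreated lay below DMSO, so that the condition over untreated added nothing there. erg was expressed in both the delta cluster (420 CPM in DAPT, 421 in DMSO) and the skeletogenic-like cells (557 and 429). The unnamed loci with the largest ratios, again chosen after their values were seen, were LOC585065 (log2 3.83, 3.48 to 4.20) and LOC575621 (log2 3.78, 2.71 to 5.05). Removing the 5% of barcodes with the most UMIs left 4 of these 7 named genes past the rule, and scaling by the median of ratios, which shifted the median of all genes by -0.17, also left 4. In both settings erg (0.96 and 0.95), blimp1/krox (0.93 and 0.88) and GATAe (0.86 and 0.87) came to lie just under 2-fold.

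**Figure D2:**
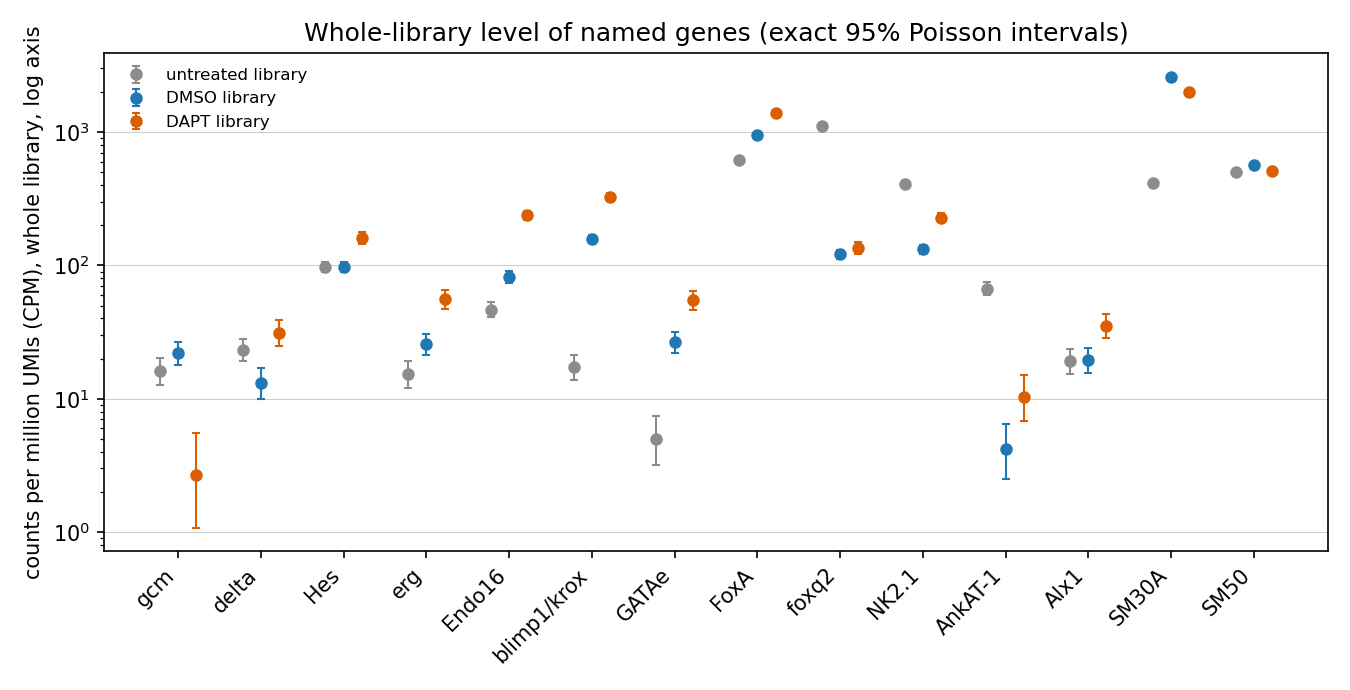
CPM of the whole library (log axis) for 14 named genes in the untreated (grey), DMSO (blue) and DAPT (orange) libraries; points give the level and bars the exact 95% Poisson interval. gcm lay far lower in DAPT, at 2.67, than in either other library, whereas SM30A and foxq2 separated the untreated library from the other 2.

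Of the fixed gene lists, the endoderm genes stood highest in DAPT relative to DMSO, with a median log2 ratio of 1.05 over 4 measured members, at percentile 100 among 10000 random lists matched on expression. In that list Endo16, blimp1/krox and GATAe were at least 1.5-fold higher, and FoxA, a foregut and endoderm factor, had a log2 ratio of 0.57 (0.50 to 0.63). The aboral ectoderm genes lay lower in DAPT (median -0.39 over 11 measured members, percentile 0.01), led by the metallothionein MTa (log2 -0.74), the arylsulfatase ARS (-0.59), spec2d (-0.57) and HMX (-0.44), with 2 members at least 1.5-fold lower. Over untreated their median was -0.0619 (percentile 15.2), so that the list as a whole was not lower against this second reference. Its members went both ways there, with 3 at least 1.5-fold lower and 2 at least 1.5-fold higher. ARS was among the lower ones (log2 -0.88, -0.89 to -0.87). The 8 skeletogenic genes had a median of -0.03 (percentile 22.0), with Alx1, the regulator of the lineage, at 0.85 (0.41 to 1.29), msp130 at 0.43, P16 at 0.40 and SM30A at -0.37.

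The 4 apical and ciliary-band genes had a median of 0.48 (percentile 93.3), with AnkAT-1 at 1.31 (27 and 19 UMIs), NK2.1 at 0.79, foxq2 at 0.16 and hnf6 at -0.31. The 6 oral ectoderm genes had a median of 0.30 (percentile 80.5), with Nk1 at 0.58, CHRD at 0.37, Not at 0.31 and Gsc at -0.69. The 3 measured blastocoelar genes went both ways (median -0.34, percentile 4.23), with erg at 1.12, GATAc at -0.38 and SRC8 at -0.34. The germline helicase vasa, the only measured small-micromere marker, stood at 0.59 (0.15 to 1.01), and cyclin A (CycA), the only measured cell-cycle gene, at 0.51 (0.36 to 0.65). The Wnt list had Wnt8, given above, and Tcf/Lef at 0.13 (-0.22 to 0.48). No gene name matched the muscle or dissociation-stress lists, so neither list was measured. The matching missed Gp96, given below within classes, which is another name of the stress-list member grp94.

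Of the Delta/Notch list, only delta, the ligand, and Hes, a repressor of the Hairy/Enhancer-of-split family, were found by name. Delta stood at 31.3 CPM in DAPT (24.9 to 38.9), 13.2 in DMSO (10.0 to 16.9) and 23.3 in untreated (19.2 to 28.1), so that it was higher in DAPT than in DMSO (log2 1.25, 0.75 to 1.76), while its ratio to untreated had an interval that included 1 (log2 0.42). Hes stood at 161 CPM in DAPT against 97.4 in DMSO and 97.5 in untreated (log2 0.72 over DMSO, 0.53 to 0.92). The delta cluster, which delta itself singled out, held 58.5% of the delta UMIs of the DAPT library, 40.0% of those in DMSO and 41.1% of those in untreated. Within that cluster the level of delta was 255 CPM in DAPT (188 to 338), 349 in DMSO (223 to 519) and 476 in untreated (348 to 634). Without the 5% of barcodes with the most UMIs these levels came closer together: 354 (256 to 477), 387 (242 to 585) and 456 (326 to 621). Apical-neurogenic-like cells carried a further 28.6% of the delta UMIs of the untreated library. Hes was spread over more classes, with 263 CPM in oral-ectoderm-like cells in DMSO and 209 in untreated. In skeletogenic-like cells, taken as background, Hes stood at 21.1 CPM in DMSO (4.35 to 61.7), 90.9 in DAPT (39.2 to 179) and 144 in untreated (71.6 to 257). In untreated the level in oral-ectoderm-like cells thus lay within the interval of the background, which rests on 11 UMIs. It lay above the interval of every other class, such as endoderm-like cells (64.6, 27.9 to 127) and all unnamed clusters together (77.5, 67.6 to 88.4). Skeletogenic-like cells are therefore an uncertain background for Hes in untreated. In DAPT, Hes stood at 340 (279 to 412) in oral-ectoderm-like and 386 (242 to 585) in apical-neurogenic-like cells. That order turned without the 5% of barcodes with the most UMIs (391 and 315).

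**Figure D3:**
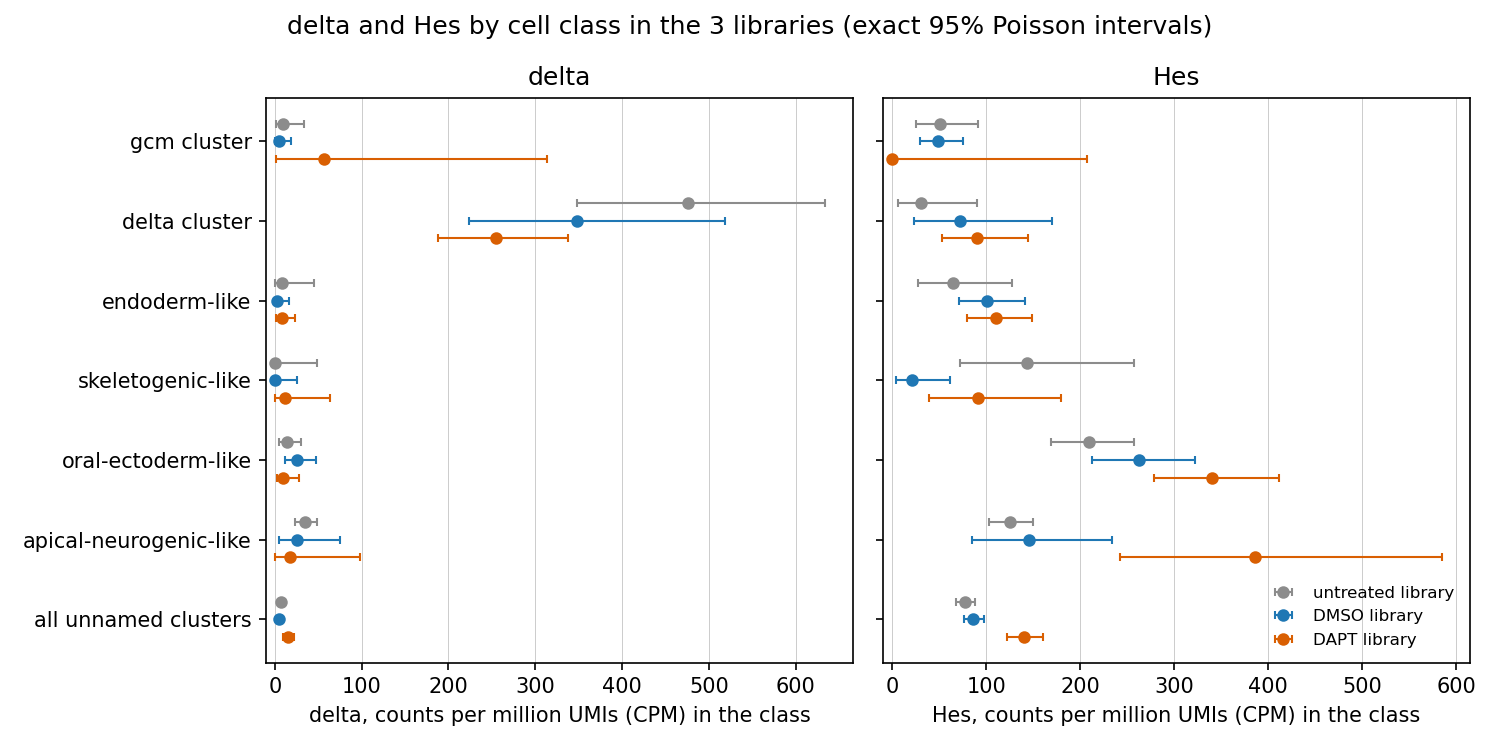
CPM of delta (left) and Hes (right) within 6 cell classes and all unnamed clusters together, for the untreated (grey), DMSO (blue) and DAPT (orange) libraries; points give the level and bars the exact 95% Poisson interval. delta was concentrated in the delta cluster, which it singled out, in each library, whereas Hes was found in most classes. In untreated, Hes in apical-neurogenic-like cells (125 CPM, 103 to 150) did not exceed that in skeletogenic-like cells, taken as background (144, 71.6 to 257). That background rests on 11 UMIs, and all unnamed clusters together stood lower (77.5, 67.6 to 88.4).

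The share of cells with at least 1 UMI of a gene does not depend on the clustering but does depend on depth, which differed between libraries. gcm was found in 0.186% of DAPT cells (0.0605% to 0.434%), 2.42% of DMSO cells (1.93% to 2.998%) and 3.05% of untreated cells (2.38% to 3.85%). In skeletogenic-like cells, taken as background, it was found in 0 of 89, 1 of 95 and 0 of 38 cells, whose median depths were 878, 1415 and 1617 UMIs; a count of 0 in 89 and 38 cells still allows shares up to 4.06% and 9.25% (exact upper limits). After each cell was thinned to 514 UMIs, which left out 266 DAPT cells and none of the others, gcm was found in 0.207%, 0.956% and 0.673% of cells. Delta was found in 2.64%, 1.55% and 3.90% of DAPT, DMSO and untreated cells before thinning and in 1.57%, 0.836% and 1.44% after it, and in 1 of 89, 0 of 95 and 0 of 38 of the skeletogenic-like cells. Endo16 was found in 8.45%, 4.63% and 4.80% before and 5.87%, 2.45% and 1.93% after thinning, against 2.25%, 2.11% and 2.63% of skeletogenic-like cells before it.

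Within classes, the comparison asks whether genes differed between DAPT and DMSO in cells of the same kind. In the oral-ectoderm-like cells (344 DAPT and 267 DMSO cells) none of 72 measured named genes met the rule of 2-fold from DMSO and 1.5-fold the same way from untreated. In the apical-neurogenic-like cells (65 and 82 cells) Hes was 2.65-fold higher in DAPT (22 and 17 UMIs, log2 1.41, 0.43 to 2.41), and ARS (log2 -1.33, -1.51 to -1.15) and the ribosomal protein gene rpl36 (log2 -1.35, -2.29 to -0.51) were lower. Without the 5% of barcodes with the most UMIs the log2 ratio of Hes was 1.26 in the same clusters, but after clustering anew Hes stood at 315 against 164 CPM, under 2-fold. With fewer UMIs than the minimum, Hes was also higher in DAPT in skeletogenic-like (8 and 3 UMIs, log2 2.11, 0.05 to 4.66) and blastocoelar-like cells (11 and 11 UMIs, 1.49, 0.14 to 2.83), so the ratio was not particular to the apical-neurogenic-like cells. Skeletogenic-like cells serve as background here, and RNA carried over from other cells was not measured. The ratios of Hes therefore do not show a change within cells of the same kind. Classes of 30 to 49 cells in the smallest library were added after the data were seen. In the endoderm-like cells rngi was then higher (2.09-fold, 23 and 10 UMIs, an interval that included 1) and Klf7 (-1.66, -3.04 to -0.45) and ARS (-1.39, -1.46 to -1.33) lower. In the skeletogenic-like cells Gp96, a chaperone of the endoplasmic reticulum, was higher (1.08, 0.42 to 1.74). FoxA was higher over DMSO there too (23 and 13 UMIs, log2 1.52, 0.47 to 2.62). It was not higher over untreated (-0.32), so the rule did not name it. ARS made up 4.06% of all DMSO UMIs and was found in each class: in skeletogenic-like cells, taken as background, it stood at 4715 CPM in DAPT and 5430 in DMSO, against 5269 and 13237 in apical-neurogenic-like and 7026 and 18476 in endoderm-like cells. RNA carried over from other cells was not measured, so the values of ARS do not show a change within cells of the same kind. In the blastocoelar-like cells FoxA (1 UMI in DAPT and 29 in DMSO, log2 -3.37, -8.72 to -0.78), CyI (-1.36, -1.70 to -1.03) and rps14 (-1.28, -2.20 to -0.46) were lower. The ratio of Gp96 was 0.87 with median-of-ratios scaling and that of rps14 -0.67 at resolution 0.5, both under 2-fold. In the delta cluster FoxA (log2 2.34, 1.04 to 4.00), SM30A (2.06, 1.02 to 3.31) and dri (1.46, -0.05 to 3.42) were higher. FoxA was also higher in the skeletogenic-like cells, as given above, so its ratio was not particular to the delta cluster. SM37 in the delta cluster (31 UMIs in DAPT and 0 in DMSO) was not higher than in untreated (log2 -0.33), so the rule did not name it. A single barcode of 33694 UMIs gave 17.9% of that cluster's DAPT UMIs, and without the 5% of barcodes with the most UMIs the ratio of SM30A turned to -0.59, that of FoxA fell to 1.36 and that of Klf7 in the endoderm-like cells to -4.12.

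The comparison of DMSO with untreated gives the size of the difference between the libraries without DAPT. Genes of the apical territory were far higher in the untreated library: AnkAT-1, named for the apical tuft, was 16.1-fold lower in DMSO (4.17 against 66.9 CPM, log2 -4.01, -4.76 to -3.34), the apical regulator foxq2 9.14-fold lower (121 against 1106, log2 -3.19, -3.32 to -3.07) and NK2.1 3.09-fold lower (log2 -1.63, -1.76 to -1.50). Genes of the endoderm were higher in DMSO, with blimp1/krox 9.11-fold (log2 3.19, 2.86 to 3.53) and GATAe 5.35-fold higher (log2 2.42, 1.78 to 3.12). The spicule matrix gene SM30A was 6.30-fold higher in DMSO (log2 2.65, 2.59 to 2.72), and the homeobox genes Hbox7 (log2 2.45, 1.94 to 2.99) and Nk1 (4.91-fold, 42 against 9 UMIs) were higher as well. fkh1 (log2 -2.14, -3.45 to -1.01) was lower in DMSO.

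The classes followed the same directions. Apical-neurogenic-like cells made up 15.1% of untreated cells (13.6% to 16.6%) and were 6.16-fold less frequent in DMSO (log2 -2.62, -2.99 to -2.27), whereas endoderm-like cells made up 2.11% of untreated cells and were 2.90-fold more frequent in DMSO (log2 1.54, 1.07 to 2.03). With each library clustered on its own these were 2.39-fold and 1.56-fold, and the endoderm-like ratio was 12.4-fold at resolution 2.0. The directions held and the sizes depend on the clustering. Skeletogenic-like cells were 1.66-fold (1.13 to 2.49) and cells of the gcm cluster 2.21-fold (1.68 to 2.96) more frequent in DMSO. The latter were 1.42-fold more frequent (1.13 to 1.81) when clustered without the 2-fold-apart genes, so that this size too depends on the clustering. The ratios of oral-ectoderm-like cells (0.871, 0.723 to 1.05), delta cluster cells (0.789, 0.516 to 1.21) and blastocoelar-like cells (1.33, 0.890 to 2.02) had intervals that included 1. The ratio of oral-ectoderm-like cells was 0.803 (0.647 to 0.996) among cells with at least 500 genes and turned to 1.40 (1.20 to 1.63) at resolution 2.0. The endoderm list had a median log2 ratio of 1.61 (percentile 99.99) with all 4 measured members at least 1.5-fold higher in DMSO, and the apical and ciliary-band list a median of -2.41 (percentile 0) with 3 of 4 members lower. The blastocoelar list stood at 0.66 (percentile 99.0), with GATAc at 1.69 (1.11 to 2.29), the aboral ectoderm list at 0.33, the oral ectoderm list at -0.10 and the skeletogenic list at -0.01. Delta was lower in DMSO (log2 -0.83, -1.30 to -0.36), and gcm was higher (0.45, 0.01 to 0.90), while Hes had a log2 ratio of -0.00 (-0.19 to 0.19).

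The comparison of DAPT with untreated serves as a second reference for DAPT. gcm (log2 -2.59, -3.95 to -1.47) was lower and the share of the gcm cluster was 5.05-fold lower (log2 -2.34, -3.22 to -1.53) in DAPT than in untreated too. The delta cluster was 3.01-fold more frequent (2.13 to 4.32) and endoderm-like cells 4.98-fold more frequent (3.64 to 6.93). Other cell filters and clusterings gave 4.50-fold (top 5% of barcodes removed) to 12.6-fold (at least 500 genes) for the gcm cluster, 2.03-fold (without the 2-fold-apart genes) to 3.16-fold (Scrublet calls removed) for the delta cluster, and 2.49-fold (each library on its own) to 21.1-fold (resolution 2.0) for endoderm-like cells. The endoderm list stood at a median of 2.90, with blimp1/krox at 4.24 and GATAe at 3.46, and the apical and ciliary-band list at -1.77, with foxq2 at -3.03. For blimp1/krox, GATAe and foxq2 the differences between DMSO and untreated were larger than those between DAPT and DMSO, whereas for Endo16 they were smaller and for gcm smaller and of opposite sign.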

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

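The removal of the 5% of barcodes with the most UMIs and the classes of 30 to 49 cells were chosen after the data were seen, whereas all other alternatives were fixed before the data were examined. No paired analysis was possible because each group has 1 library, and no library could be left out. Of the values that answer a comparison, 135 stayed within their counting interval under an alternative, 20 left it and 1 reversed; of the others, 154 stayed, 47 moved and 2 reversed. A change of sign was counted as reversed only where the interval of the first value excluded 0, and otherwise as having left its interval or stayed in it. The lower share of the gcm cluster and the higher share of the delta cluster in DAPT over DMSO stayed within their intervals in each cell filter and clustering that gave a value, while over untreated in place of DMSO the share of the gcm cluster was -2.34 on the log2 scale, outside its interval. With each library clustered on its own, no DAPT cluster could be named the gcm cluster. The name needs at least 20 gcm UMIs and the DAPT library holds 7, so its absence there shows nothing about the cells. Blastocoelar-like cells were named in neither that setting, nor without the 2-fold-apart genes, nor without the top 5% of barcodes. Log2 values follow, and where no construction is given the cause was not tested. The share of the gcm cluster, DMSO over untreated, fell to 0.61 with at least 500 genes, 0.53 at resolution 0.5, 0.54 with each library clustered on its own and 0.51 without the 2-fold-apart genes, all settings in which this cluster held more untreated cells. With at least 500 genes the share of endoderm-like cells, DAPT over DMSO, was 1.24. At resolution 2.0 the shares over untreated in DMSO were 3.63 for endoderm-like and 0.48 for oral-ectoderm-like cells, whose direction turned, and the share of blastocoelar-like cells, DAPT over DMSO, was -3.14. With each library clustered on its own, the endoderm-like share, DMSO over untreated, was 0.64, and the apical-neurogenic-like share -0.78 for DAPT over DMSO and -1.25 for DMSO over untreated. Median-of-ratios scaling lowered the median of all genes by 0.17 (-0.17) for DAPT over DMSO and put the skeletogenic list at -0.20 and the aboral ectoderm list at -0.57; a member minimum of 10 put the skeletogenic list at 0.11, so its sign is not settled. With untreated as the reference for DAPT, the lists stood at 1.31 (blastocoelar), 2.90 (endoderm), -0.0619 (aboral ectoderm) and -1.77 (apical and ciliary band, reversed). The share of cells with gcm was -2.21 after thinning and -2.27 with at least 2 UMIs, where fewer cells count, and that with Hes -0.00932 with at least 2 UMIs (reversed). By share of cells, delta in the delta cluster over other cells of untreated was 4.44. SM30A within the delta cluster reversed to -0.59 without the top 5% of barcodes, which hold the barcode of 33694 UMIs. Of the 7 genes reported for DAPT over DMSO, 4 (top 5% removed) to 7 (lower minimums) remained, and of the 9 for DMSO over untreated, 8 or 9 under the other scalings and cell filters. With lower minimums 4 of these 9 were among the 5 largest each way, since genes of lower count took the other places; the ratios themselves do not depend on the minimum.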

Other observations

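The tests of explanations below were all chosen after the results they bear on were seen. Within skeletogenic-like cells the spicule matrix genes did not go together between libraries. SM30A stood at 23772 CPM in untreated, 79938 in DMSO and 55585 in DAPT, whereas SM50 (28313, 17296 and 13476), SM37 (34915, 17662 and 12885) and PM27 (27556, 14370 and 11385) were each highest in untreated. SM30A over untreated was higher in both other libraries (log2 1.75 in DMSO and 1.23 in DAPT) while SM50 was lower (-0.71 and -1.07). msp130, a cell surface protein of the same lineage, stood at 678, 563 and 454 CPM.

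The class called endoderm-like also differed in expression between the libraries without DAPT. At resolution 2.0 it held 186 DMSO but only 10 untreated cells (log2 share ratio 3.63), against 205 and 47 in the clustering at resolution 1.0, so the levels that follow may compare different cells. In the clusters used here, blimp1/krox stood at 1757 CPM in DMSO and 2029 in DAPT against 412 in untreated, and GATAe at 292 and 331 against 64.6, while Endo16 stood at 917, 1480 and 1091 and FoxA at 7140, 5123 and 4096. In oral-ectoderm-like cells foxq2 stood at 1616 CPM in untreated against 243 in DMSO and 286 in DAPT, so that its higher level in untreated was not limited to apical-neurogenic-like cells (3950, 2555 and 2459). In the delta cluster it stood at 1510 CPM in untreated, 290 in DMSO and 266 in DAPT.

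The first pattern weighed is the small number of gcm cluster cells in DAPT. Lower depth of the DAPT library is argued against by the cells with at least 500 detected genes, of which 0.400% in DAPT and 7.64% in DMSO were in the gcm cluster, a log2 ratio of -4.26 (-6.15 to -2.87). That filter did not equalise depth, with medians of 1122 UMIs in DAPT and 1474 in DMSO. After thinning to 514 UMIs the share of cells with a UMI of gcm still had a log2 ratio of -2.21 (-3.93 to -0.84), with 0.207% against 0.956%, where it was 0.186% against 2.42% before. A lower level of gcm alone, in cells otherwise present, is argued against by 84 other genes at least 10-fold enriched in this cluster of the untreated library. Over whole libraries their median log2 ratio was -2.73 (quartiles -3.53 to -1.32), with 69 at least 2-fold lower and 8 higher. These genes were picked from the joint clustering of the same libraries. Loss of all mesenchyme cells in handling is argued against by the share of skeletogenic-like cells, with a log2 ratio of 0.22 (-0.21 to 0.66). An effect of blocking Notch cleavage on the forming of these cells, a selective loss of these cells in handling, the whole programme being silent in cells that then joined other clusters, and a difference between cultures stay open with 1 library per group.

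The second pattern is the larger delta cluster in DAPT. Lower depth of the DAPT library is argued against only in part by the cells with at least 500 detected genes. Among these the share of the delta cluster had a log2 ratio of 1.76 (1.11 to 2.44), but the filter did not equalise depth. It left median depths of 1122 UMIs in DAPT and 1474 in DMSO, and kept 37.3% and 64.5% of the barcodes. After thinning, the share of cells with a UMI of delta was 1.57% in DAPT (1.11% to 2.15%) and 0.836% in DMSO (0.556% to 1.21%). It was thus still higher in DAPT than in DMSO, with intervals that overlapped slightly. In untreated it was 1.44% (0.984% to 2.02%), close to DAPT. More delta UMIs drawing cells into the cluster is argued against, as the whole cause, by the clustering without the 2-fold-apart genes. There the share still had a log2 ratio of 1.53 (0.96 to 2.12). The cluster then held 88 DAPT cells in place of 156 and 38 DMSO cells in place of 51, and delta still named it. A part of the excess owed to the differing genes is therefore not excluded. Doublets of high UMI count are argued against by the share without the top 5% of barcodes, 1.93 (1.45 to 2.43). More cells of this kind under Notch inhibition and a difference between the 2 cultures both stay open, since no test with 1 library per group can decide between them.

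The third pattern is the higher apical and lower endoderm expression of the untreated library relative to DMSO. Its greater depth is argued against by the thinned share of cells with a UMI of foxq2, 3.58% in DMSO and 24.4% in untreated, a log2 ratio of -2.77 (-3.07 to -2.48), against 6.69% and 41.4% before thinning and 0 of 95 and 5 of 38 skeletogenic-like cells. Over-capture of 1 class that dilutes all others alike is argued against by the share ratios of endoderm-like and oral-ectoderm-like cells, which differed by 1.58 on the log2 scale when clustered without the 2-fold-apart genes. A stage, culture or compound that the label does not give cannot be told apart from the DMSO itself. The C59 that the protocol describes would be such a compound. The endoderm list stood at a median of 1.61, and 1 library per group and the missing stage keep the question open.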
